A study of Homo sapiens with 5 samples.

How the data were processed

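Jurkat cells were untreated or treated with chidamide, decitabine or both, and H3K4me3 was profiled by chromatin immunoprecipitation and paired-end sequencing with reads of 150 bases, per the labels' protocols. The series has 5 samples, of which 4 are H3K4me3 libraries and 1 is input DNA from untreated cells. Each group has 1 library. The treatment was taken from the treatment label of each sample, and the untreated library and the input from their titles. The labels give the doses as 5nm and 5μm, read as nanomolar and micromolar. Treatment time is not given in the sources used here.

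The authors deposited 1 peak list per H3K4me3 library, called against the untreated input as the names of the lists say. Each line gives a chromosome, a start, an end, a peak name of the form MACS_peak and a score. The deposited score has no header that states its scale. Its lowest value is about 60 and its highest 3233.06, with many peaks at 3100, so strong peaks cannot be ranked against each other. It was used to rank or filter peaks within a list. Cut-offs at the same score in several lists do not make the lists equally strict, because a score depends on depth. The submitters' processing notes name CASAVA 1.8, Bowtie2 and the hg19 build. The Bowtie2 version, the MACS version, the peak caller's settings, the handling of duplicate reads and the read depths are not given in the sources used here. A deeper or more enriched library gives a longer list at the same threshold, and a fragment length or smoothing setting that differs between libraries changes how a domain is divided into peaks. No profile of the input was analysed here. All comparisons use hg19 coordinates, written from 1.

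A peak counted as shared with another list if a peak of that list overlapped it by at least 1 bp. A gained peak is a peak of a treated list that no untreated peak overlaps, and a lost peak is an untreated peak that no treated peak overlaps. Overlapping peaks of the 4 lists were joined into regions, and each region was described by the lists that hold it. A gained peak can lie in a region of the untreated list where a peak of another list bridges the gap. Spans run from the start of the first to the end of the last peak of a list in a region. The 4 classes of region width were set from lists that do not enter the difference shown. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. No test between conditions was run, since no group has a replicate.

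The number of regions expected from list length alone came from a Rasch-type model, in which a region's chance of being listed depends on the region and the list. The list effects were fitted by conditional likelihood given how many lists hold a region, and 1000 sets of lists were drawn with a fixed seed. The model keeps the number of regions held by 1, 2, 3 or 4 lists as observed, so an effect in one pair of lists also moves the values expected elsewhere. For overlaps of gained or lost regions, the product of the list sizes over the number of regions was computed too.

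The overlap code was checked on the deposited lists and the model on simulated lists. All 24 overlap counts equalled those of bedtools 2.31.1. With no treatment effect simulated, 15 of 15 combinations of lists lay inside the range of draws. Those lists were simulated from the same kind of model, so this checks the fitting and not whether the model suits the deposited lists. With 500 regions added to the chidamide and combination pair, the count lay above every draw, but the excess over the model was 225.8, so the model takes up part of a true excess. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

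Regions named in the text follow a rule set before the data were examined, namely the 10 gained and the 10 lost peaks with the highest score in each comparison with the untreated list and the 10 highest-scoring peaks held by the combination list alone, on chromosomes 1 to 22 and X. Equal scores were ordered by chromosome name and position. The regions shown as members of a pair of lists, the block on chromosome 1 and the regions with the longest differences in span were chosen after the values were seen, as the highest of their kind. The rule also covered 9 genes and members of 17 gene lists (T cell identity, MAPK signalling, apoptosis, cell cycle, chromatin modifiers, germline genes, interferon response, tumour suppressors and others). These parts, the share of peaks at promoters and the genes with a promoter peak gained or lost were not run, because the lists name no genes and the gene table at hand is of another genome build than hg19. No gene is named for any region for the same reason.

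Alternatives set before the data were examined were an overlap of 50% of the shorter peak, a reciprocal overlap of 50%, peaks scoring at least the untreated median of 740.475, lists limited to their best 20136 peaks, merging of peaks less than 1 kb apart, and autosomes only. Leaving out the combination list was added after the data were seen. With 1 library per group, no library could be left out in turn, no replicate numbers could pair the libraries, and the control could not be split.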

Results

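Chromatin immunoprecipitation followed by sequencing measured trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of the promoters of transcribed genes, in Jurkat cells, a human T cell acute lymphoblastic leukaemia line. The labels mark the cells as carrying an amino acid change in KMT2D, an H3K4 methyltransferase. There were 4 H3K4me3 libraries. The cells of the first were untreated, those of another received chidamide, a benzamide inhibitor of histone deacetylases, and those of another received decitabine, a cytidine analogue that traps DNA methyltransferases. The cells of the last received both drugs. Each drug was given at a label value of 5, spelled nm for chidamide and μm for decitabine and read here as nanomolar and micromolar. On that reading the chidamide concentration is low for this drug, so its dose is uncertain. The fifth library was input DNA of untreated cells, which the names of the peak lists give as the control of every list. The design sets each drug, and the pair of drugs, against no treatment and sets the pair against each drug alone.

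Every group had 1 library, so no difference between conditions could be set against a replicate spread and none was tested. The intervals given are 95% exact (Clopper-Pearson) binomial intervals over peaks or regions. They cover counting error only, because peaks of a library are not replicates. The lists give no read counts, so the depth behind each list is unknown. The score of a peak is the authors' own and was used to rank or filter peaks within a list. Its lowest value in every list was about 60, and many peaks sat at 3100, near its upper end.

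The 4 lists differed in both the number and the width of their peaks. The untreated list held 23262 peaks over 63.22 Mb, with a median width of 2051 bp. The chidamide list was longer, at 27070 peaks over 74.22 Mb, with a median width of 1800 bp. The decitabine list was the shortest, at 20136 peaks over 69.19 Mb, and its peaks were the widest, with a median of 2992.5 bp. The combination list held the most peaks, 40666, yet covered the least sequence, 57.73 Mb, because its median width was 669 bp. Peaks of 5 kb or wider made up 15.19% of the untreated list, 16.82% of the chidamide list, 23.31% of the decitabine list and 4.584% of the combination list.

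Many of the combination list's peaks lay side by side. In that list 52.95% of the peaks (interval 52.46 to 53.43%) began less than 1 kb after the end of another, against 25.77% (25.21 to 26.34%) in the untreated list, 28.71% (28.17 to 29.25%) in the chidamide list and 12.7% (12.25 to 13.17%) in the decitabine list. Once peaks of a list less than 1 kb apart were merged, the 4 lists held 17267, 19298, 17578 and 19135 peaks in the same order of untreated, chidamide, decitabine and combination. Counts of gained or lost peaks therefore count parts of domains more often in the combination list than in the other 3.

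**Figure D1:**
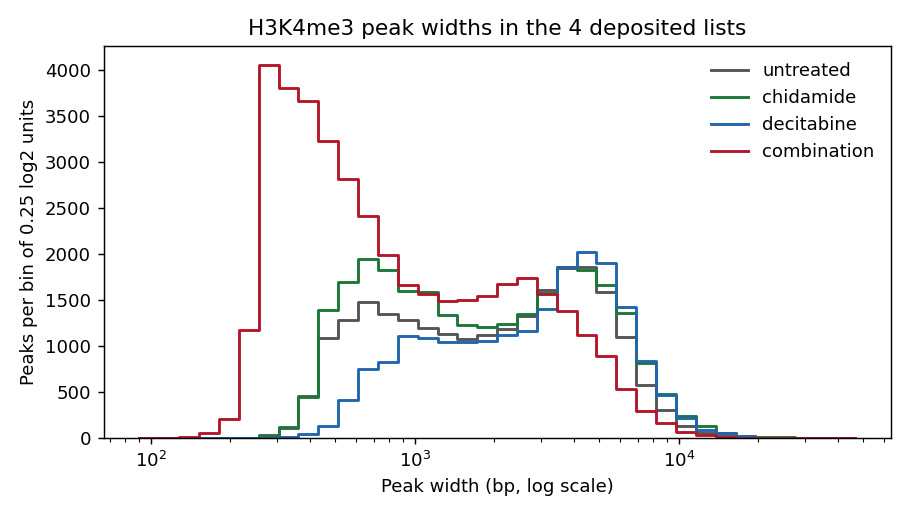
Width of the H3K4me3 peaks of each of the 4 libraries. The horizontal axis is peak width in bp on a log scale, the vertical axis is the number of peaks per width bin, and each line is 1 library. The combination list has its bulk of peaks below 1 kb, with a median of 669 bp, and the decitabine list has the fewest narrow peaks, with a median of 2992.5 bp.

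The comparison of chidamide with no treatment asked which H3K4me3 regions were listed with the histone deacetylase inhibitor and not without it. The chidamide list held strong and wide peaks at places where the untreated list had none. Among them were chr17:42446691-42452328 (5638 bp wide, score 3223.06), chr19:40669960-40676179 (6220 bp, score 3198.77) and chr19:46473851-46476790 (2940 bp, score 3148.08). A pair of peaks lay on chromosome 5, at 1132171 to 1138863 and at 1167398 to 1174752, each with a score of 3100. In all, 12 gained peaks scored 3100 or more, and ties at 3100 were ordered by chromosome name and position. The 10 taken by this order had scores of 3100 to 3223.06 and widths of 2940 to 7701 bp, and all 10 were overlapped by a peak of the combination list. Of the 10, 3 were also overlapped by a decitabine peak, at chr12:57522390-57526786, chr1:23035058-23041582 and chr1:15476430-15483478. In the decitabine list the best score was 71.92 at the second of these places and 147.06 at the third, where the untreated list had no peak. At the place on chromosome 12 the untreated list did hold a neighbouring part of the same domain, with a score of 737.76. The others at 3100 lay in chr6:3713262-3720335 and chr7:100992521-101000325, regions of the chidamide and combination lists alone.

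In total, 19646 of the 27070 chidamide peaks (72.57%, interval 72.04 to 73.11%) were overlapped by an untreated peak by at least 1 bp, and 7424 were not. Most of the gained peaks were weak, with a median score of 92.07, but 1728 scored 150 or more and 264 scored 500 or more. A further measure of position was the merged domain, and 944 of the 7424 gained peaks lay in a domain that the untreated list also reached.

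Losses under chidamide were fewer, and most lost peaks scored low for the untreated list, whose median was 740.475. Of the 23262 untreated peaks, 2913 (12.52%) had no chidamide peak over them, with a median score of 85.26 and with 10 scoring 500 or more. All 6181 untreated peaks at the score ceiling were overlapped by a chidamide peak. The 10 highest-scoring lost peaks had scores of 503.02 to 925.6. At chr6:32011254-32014082 (score 837.75) and chr18:9848694-9851574 (score 503.02) the untreated and decitabine lists held peaks and the lists of both libraries with chidamide held none. At chr12:14537758-14540454 (score 799.84), chr4:127837139-127839813 (score 714.81), chr11:78059739-78062410 (score 646.56) and chr8:106375876-106377484 (score 505.54) there was no chidamide peak. At these 4 places the highest scores in the combination list were 90.56, 78.74, 107.3 and 103.22. At chr4:139156628-139158832 (score 925.6) and chr18:48724159-48725795 (score 718.08) the lost peak was part of a domain that all 4 lists held with scores of 2608 or more. With a reciprocal overlap of 50% the gained peaks numbered 11706 and the lost peaks 7898, and with each list limited to its best 20136 peaks the gained peaks numbered 3131.

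**Figure D2:**
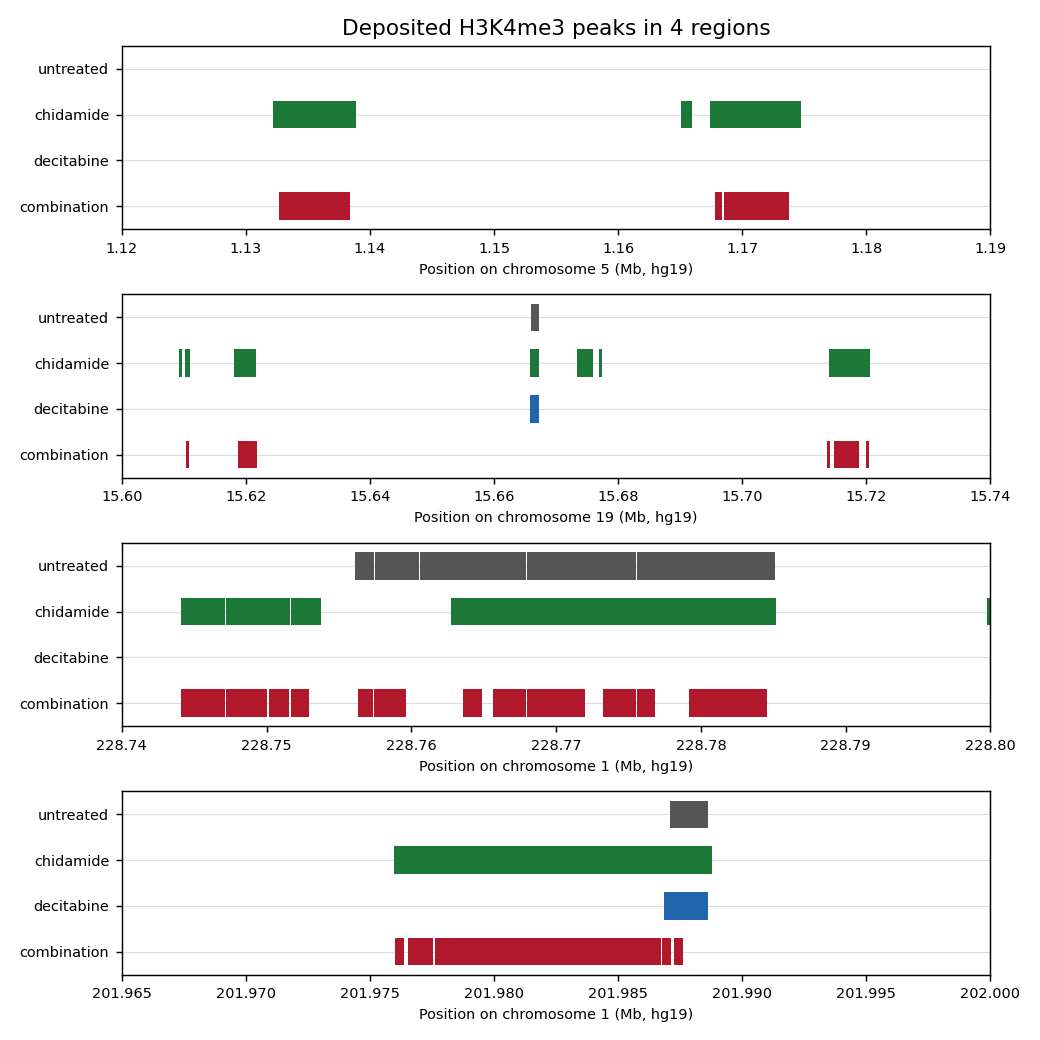
Peaks of the 4 libraries, drawn to scale as bars, in 4 regions of the hg19 genome, with the position in Mb on the horizontal axis and a line for each library. The upper 2 maps show places on chromosomes 5 and 19 where the chidamide and combination lists hold peaks scoring up to 3100 and the untreated list holds few or none. The third map shows the block on chromosome 1 without a decitabine peak, and the last map shows a domain of 12835 bp in the chidamide list that spans 1523 bp in the untreated list.

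The comparison of decitabine with no treatment asked the same of the DNA methyltransferase inhibitor. Most decitabine peaks lay on untreated peaks, and the gained ones were few and weak. The highest-scoring of them lay at chr5:130717271-130720313 (3043 bp wide, score 579.83), chr8:72271281-72273861 (2581 bp, score 420.74), chr3:137918176-137920036 (1861 bp, score 411.53) and chr13:97907245-97908854 (1610 bp, score 392.19). Of the 10 highest-scoring gained peaks, 4 had no overlapping peak in any other list, among them those at chr8:72271281-72273861, chr6:113277175-113279455 (score 361.62) and chr17:33377599-33379295 (score 340.03).

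Of the 20136 decitabine peaks, 17619 (87.5%, interval 87.04 to 87.95%) were overlapped by an untreated peak and 2517 were not. The gained peaks had a median score of 78.66, with 199 scoring 150 or more and 1 scoring 500 or more. By contrast, 264 chidamide peaks and 160 combination peaks without an untreated peak scored 500 or more, a difference between lists of unequal length that was not tested.

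The highest-scoring losses under decitabine came from 1 place. The untreated list held 6 peaks in a block of 28989 bp at chr1:228756129-228785117, which covered 28765 bp and scored up to 1633.22. The decitabine list held no peak in the block. The chidamide list held 1 peak there, 22354 bp of it inside the block, with a score of 66.06, and the combination list held 11 peaks over 19666 bp with scores up to 518.61. Directly beside the block, from 228744100 to 228753751, the chidamide list held 3 peaks scoring up to 429.1 and the combination list 4 peaks scoring up to 177.27, where the untreated and decitabine lists held none. Whether the block is repeated sequence, where reads can be placed ambiguously, was not examined. The 5 highest-scoring lost peaks all lay in this block. Other losses were chr16:88564190-88566426 (score 512.51), which the chidamide list held at 306.74, and chr8:142411662-142412726 (score 433.97), which no other list held. In all, 2472 of the 23262 untreated peaks (10.63%) had no decitabine peak over them, with 6 scoring 500 or more, and all 6181 untreated peaks at the score ceiling were overlapped. The reciprocal overlap of 50% gave 4509 gained and 7635 lost peaks, and lists limited to 20136 peaks gave 3138 gained and 1079 lost peaks, against 3131 gained for chidamide at that length.

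The comparison of the combination with no treatment asked which regions were listed when both drugs were given. The strongest gained peaks stood at places that the chidamide list held as well. They included chr1:201977606-201986730 (9125 bp wide, score 3100), chr19:15714749-15718795 (4047 bp, score 3100), chr5:1133373-1138350 (4978 bp, score 2960.63), chr1:32041692-32046707 (5016 bp, score 2829.64) and chr5:1168507-1173796 (5290 bp, score 2724.81). All 10 of the highest-scoring gained peaks were overlapped by a chidamide peak, and 4 of them were also overlapped by a decitabine peak. At 3 of those 4 places the untreated list had no part of the domain and the best decitabine score was low, with 105.89 at chr17:26295182-26298960, 70.18 at chr12:57407267-57410364 and 147.06 at chr1:15476731-15481208. The peak at chr2:108344769-108349900 was part of a domain that all 4 lists held at 3100. The peak at chr1:201977606-201986730 was part of a domain that the untreated and decitabine lists also reached, with scores of 156.86 and 111.66.

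Of the 40666 combination peaks, 30351 (74.63%, interval 74.21 to 75.06%) were overlapped by an untreated peak and 10315 were not. The gained peaks had a median score of 81.23, with 1548 scoring 150 or more and 160 scoring 500 or more. Of the 10315, 3954 lay in a domain that the untreated list also reached. A chidamide peak but no decitabine peak overlapped 4790 of the gained peaks (46.44%, interval 45.47 to 47.41%). A decitabine peak but no chidamide peak overlapped 640 of them (6.205%, 5.747 to 6.687%), peaks of both lists overlapped 1740 (16.87%, 16.15 to 17.61%), and 3145 (30.49%, 29.6 to 31.39%) were in no other list.

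Untreated peaks without a combination peak numbered 4381 of 23262 (18.83%), and all 6181 at the score ceiling were overlapped. Of the 4381, 1506 (34.38%, interval 32.97 to 35.8%) were overlapped in both single-agent lists, 1223 (27.92%, 26.59 to 29.27%) in the decitabine list alone, 534 (12.19%, 11.23 to 13.19%) in the chidamide list alone, and 1118 (25.52%, 24.23 to 26.84%) in neither. The highest-scoring lost peaks lay at chrX:79679355-79681815 (score 1060.15), chr20:31229228-31232138 (score 958.7), chr1:223975043-223977686 (score 917.41), chr5:96077634-96080075 (score 868.06) and chr9:80522009-80524886 (score 864.31). Each of these 5 was overlapped in both single-agent lists. The combination list also reached the domain on chromosome X, with a score of 62.22. At the places on chromosomes 1, 5 and 9 the chidamide list scored 63.56, 83.91 and 60.9, close to its lowest values, while the decitabine list scored 1075.16, 1108.69 and 753.52. The reciprocal overlap of 50% turned the 30351 shared combination peaks into 12537 and the 10315 gained ones into 28129. Merging peaks less than 1 kb apart gave 4012 gained and 2353 lost peaks. Gains did not outnumber losses in every setting, since lists limited to 20136 peaks gave 1236 gained and 5358 lost, and peaks scoring 740.475 or more gave 457 gained and 1644 lost.

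Against the single agents, the order of the overlaps depended on the list that was counted. Chidamide peaks overlapped 35694 of its 40666 peaks (87.77%, interval 87.45 to 88.09%) and decitabine peaks overlapped 31391 (77.19%, 76.78 to 77.6%). In the other direction, combination peaks overlapped 20541 of the 27070 chidamide peaks (75.88%, 75.37 to 76.39%) and 16516 of the 20136 decitabine peaks (82.02%, 81.48 to 82.55%). All of these shares depend on the lengths and covered sequence of the lists, and no difference between them was tested. Combination peaks without a chidamide peak scored low, with a median of 72.37 and with 1 of 4972 at 500 or more. Those without a decitabine peak numbered 9275, of which 165 scored 500 or more.

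The 3145 combination peaks absent from all 3 other lists were narrow and weak. The highest-scoring of them were chr19:15955398-15956234 (837 bp wide, score 284.21), chr9:67792722-67794044 (1323 bp, score 268.58), chr12:48588887-48589737 (851 bp, score 217.99) and chr17:75567547-75568048 (502 bp, score 212.45). Their median score was 70.71 and 50 of them scored 150 or more. When every list was limited to its best 20136 peaks, 45 combination peaks were absent from the other limited lists. With every list cut at a score of 740.475, 23 were absent from the others. None of the 3145 reached that score, so another full list holds a peak over each of those 23 at a score below the cut.

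Peaks of the 4 lists joined into 29430 regions. Of these, 14643 (49.76%) were held by all 4 lists, 9584 by 1 list, 3533 by 2 lists and 1670 by 3 lists. Regions held by the chidamide and combination lists and by neither of the others numbered 1963, the most of the 6 pairs. Regions held by the untreated and decitabine lists alone came next, with 719. The other pairs held 311 (untreated and chidamide), 253 (chidamide and decitabine), 156 (decitabine and combination) and 131 (untreated and combination).

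Among the regions of the chidamide and combination pair were chr19:15713673-15720532, with scores of 3100 in both lists, chr12:52278937-52284646 (2869.29 and 2347.02), chr19:47970992-47975255 (2891.08 and 1875.7), chr9:132512221-132516856 (2562.17 and 1839.75) and chr1:154643910-154650784 (2524.79 and 1798.87). The untreated and decitabine pair held chr6:32011075-32014082 (837.75 and 623.69), chr12:46271400-46273670 (416.75 and 435.86), chr6:131967366-131970101 (407.68 and 877.75) and chr18:9848694-9851674 (503.02 and 404.27). Regions scoring 150 or more in both lists numbered 463 for the chidamide and combination pair, 131 for the untreated and decitabine pair, 10 for untreated and chidamide, 4 for chidamide and decitabine, and 0 for the remaining 2 pairs.

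Longer lists hold more regions by length alone, so the counts were set beside a model in which a region's chance of being listed depended on the region and on the list's length, with no treatment effect. For the chidamide and combination pair the model gave 1214.9 regions (range of 1000 draws 1135 to 1314) against the 1963 observed. For the untreated and decitabine pair it gave 220.8 (175 to 268) against 719. The other 4 pairs lay below the model, for example chidamide and decitabine with 253 against 629 (564 to 705). The model keeps the total of regions held by 2 lists as observed, so an excess in some pairs forces a shortfall in others. These shortfalls are therefore no separate result. Regions held by all lists but the combination numbered 714 against 289.2 (245 to 341). With a reciprocal overlap of 50% the count of the chidamide and combination pair fell below the model, at 1740 against 2015.5, while the untreated and decitabine pair stayed above it, at 1296 against 305.5. In that setting the chidamide and decitabine pair (544 against 433.6) and the untreated and chidamide pair (836 against 621.2) also lay above the model. With lists limited to 20136 peaks the order of the pairs changed, to 434 for chidamide and combination and 1303 for untreated and decitabine, with 57.1 and 681.6 in the model.

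**Figure D3:**
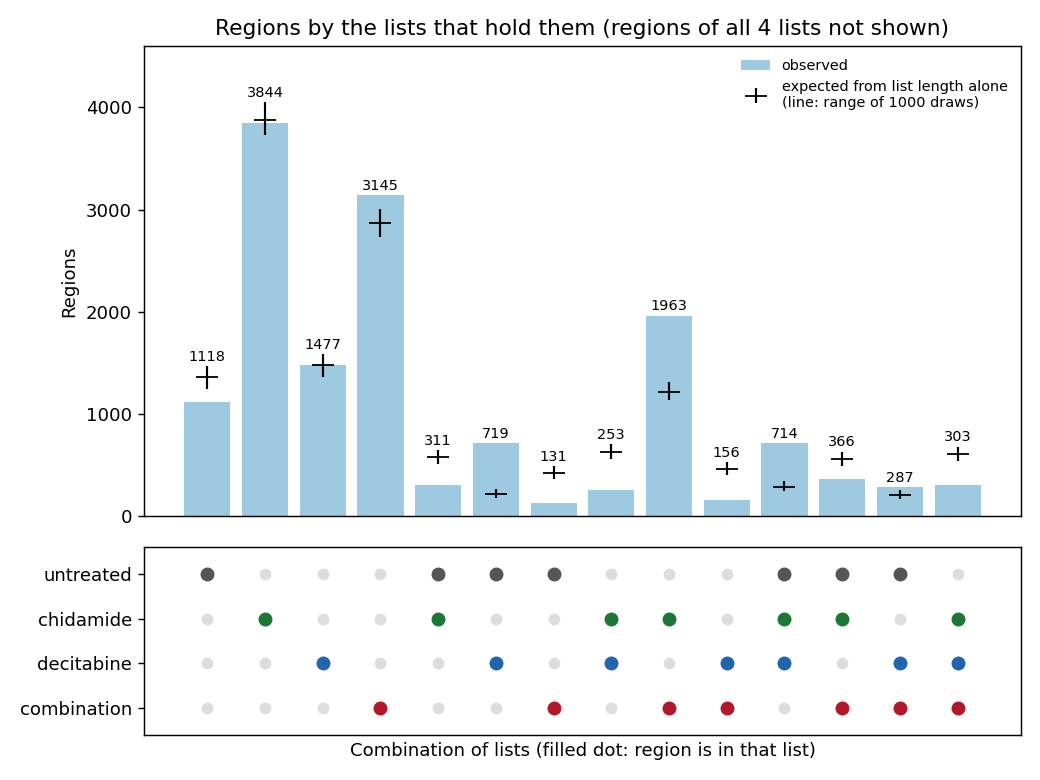
Number of regions held by each combination of lists (bars, in regions) beside the number expected from list length alone (dash, with a line for the range of 1000 draws), for regions held by fewer than 4 lists. Filled dots under each bar mark the lists that hold the regions. The chidamide and combination pair (1963) and the untreated and decitabine pair (719) stand above the model's ranges. So do the combination list alone (3145), all lists but the combination (714) and all lists but chidamide (287). The chidamide list alone and the decitabine list alone lie within their ranges, and all remaining bars lie below theirs.

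The overlap of the regions gained by the 2 single agents was counted. Of 11141 regions not in the untreated list, 6363 were in the chidamide list and 2189 in the decitabine list, and 556 were in both. Independent lists of those sizes would share 1250.2, and the model without a treatment effect gave 1238.7 (1122 to 1327). The 11141 include only regions held by at least 1 list, which makes the number for independent lists too high. The model's fixed totals can also raise its value where other combinations of lists are in excess. Counts below these references therefore do not show that the drugs gained different regions. Regions gained in both the chidamide and combination lists numbered 2266, against 3179.5 for independent lists and 1825.8 (1720 to 1930) in the model. Regions gained in both the decitabine and combination lists numbered 459, against 1093.8 and 1073.7 (981 to 1157).

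Untreated regions absent from both single-agent lists numbered 1249, against 237.5 for independent lists and 1785.5 (1676 to 1916) in the model. Absent from both the chidamide and combination lists were 1837 regions, against 352.9 and 1580.7 (1460 to 1697), and from both the decitabine and combination lists 1429, against 301.4 and 1937.2 (1804 to 2078). All of these comparisons share the untreated list, and with 1 untreated library it could not be split, so part of any excess over independent lists can come from that list. Shortfalls against the model can follow from its fixed totals here too.

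Within the 14643 regions that all 4 lists held, the stretch from the start to the end of a list's peaks differed between lists. The median span was 3815 bp in the untreated list, 4153 bp in the chidamide list, 4092 bp in the decitabine list and 3545 bp in the combination list. The decitabine list held 9.486% of these regions as more than 1 peak (interval 9.016 to 9.972%) and the combination list 67.53% (66.76 to 68.29%), against 26.31% (25.59 to 27.03%) in the untreated list and 25.59% (24.88 to 26.3%) in the chidamide list.

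The longer spans under chidamide lay mostly in wide domains. With regions sorted into 4 classes of similar size by their width in the decitabine and combination lists, the median difference between the chidamide and untreated spans was 94 bp in the narrowest class, 187 bp in the second, 338.5 bp in the third and 584.5 bp in the widest. For decitabine, with classes set by the chidamide and combination lists, the values were 236, 249, 275 and 330 bp. Spans longer by at least 1 kb in both the chidamide and combination lists than in both others were found in 673 regions, and 90 of these were longer by at least 3 kb. The reverse, longer in both the untreated and decitabine lists, was found in 270 regions, of which 8 passed 3 kb. At chr1:201975957-201988791 the spans were 1523 bp untreated, 12835 bp with chidamide, 1789 bp with decitabine and 11588 bp with the combination. At chr6:119640230-119676848 they were 28381, 36619, 29458 and 36326 bp in the same order, and at chr12:8077278-8091615 they were 5886, 13652, 6590 and 13273 bp.

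The sets of regions were spread differently over the chromosomes, a comparison chosen after the data were seen. Chromosome 19 held 191 of the 1963 regions of the chidamide and combination pair (9.73%, interval 8.454 to 11.13%), against 7.423% (7.004 to 7.86%) of the regions of all 4 lists. It held 2.234% (1.543 to 3.124%) of the regions of the decitabine list alone, 3.477% (2.263 to 5.09%) of those of the untreated and decitabine pair and 4.96% (4.228 to 5.778%) of those of the combination list alone. For the chidamide list alone the share was 8.091% (7.248 to 8.998%) and for the untreated list alone 7.424% (5.956 to 9.12%), both close to that of all 4 lists. Chromosome 8 held 6.229% (5.051 to 7.585%) of the decitabine-only regions against 3.749% (3.447 to 4.07%) of those of all 4 lists, and chromosome 5 held 6.432% (5.235 to 7.806%) against 4.5% (4.17 to 4.849%). The decitabine-only share was also smaller on chromosomes 16 (3.25% against 4.658%), 17 (3.318% against 5.812%) and 22 (1.693% against 2.513%), which like chromosome 19 are GC-rich. On the GC-poor chromosomes 4 and 13 it was larger, at 4.198% against 3.135% and 2.302% against 1.673%. The intervals overlapped on chromosomes 22, 4 and 13, and a GC trend in this set was not tested. Chromosome X held 1.885% (1.331 to 2.589%) of the chidamide and combination pair against 3.087% (2.813 to 3.38%). No test between these sets was run, and neighbouring regions are not independent.

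**Figure D4:**
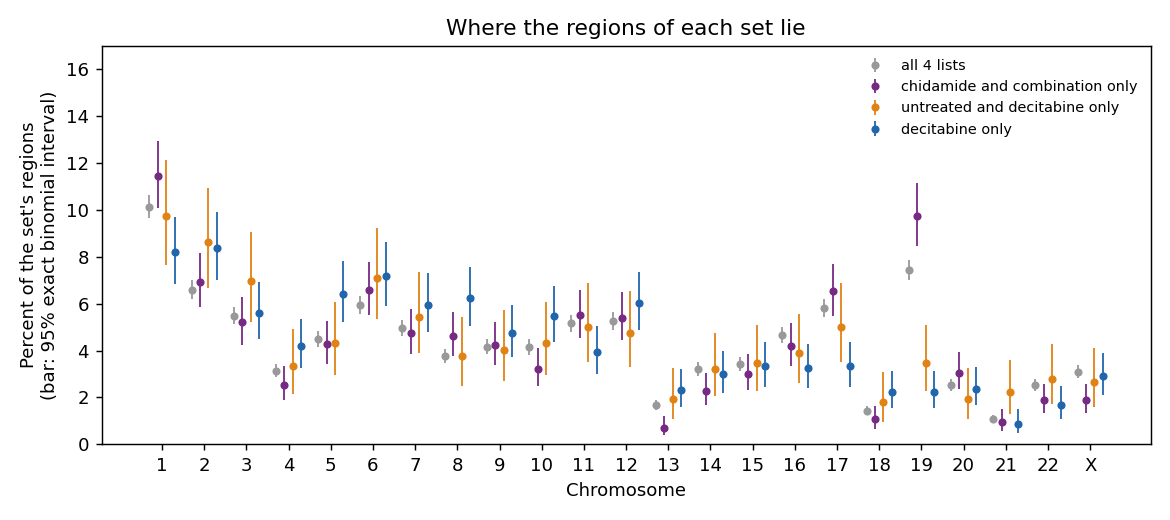
Percent of the regions of each of 4 sets that lie on each chromosome, with 95% exact binomial intervals as bars. Chromosome 19 holds 9.73% of the regions of the chidamide and combination pair, 7.423% of those of all 4 lists and 2.234% of those of the decitabine list alone.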

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

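The tests of splitting and of the span loss against the chidamide list were chosen after the results were seen. So was a lower bound of 0.5 on the ratio of span losses, which was added to the bound of 2 set before the result was seen.

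Decitabine and chidamide differed in the direction of some list properties depending on the other drug. With 1 library per group, none of these differences was tested. The number of peaks differed by -3126 between decitabine alone and no treatment, while the combination list held 13596 more than the chidamide list. Both directions turned once peaks less than 1 kb apart were merged, with 17578 peaks for decitabine against 17267 untreated and 19135 for the combination against 19298 for chidamide. Among peaks scoring 740.475 or more the combination list also held fewer than the chidamide list, 11712 against 11855. Covered sequence was 5.97 Mb larger with decitabine alone than without treatment, and the combination differed from chidamide alone by -16.49 Mb. Chidamide alone covered 11 Mb more than no treatment, and the combination differed from decitabine alone by -11.46 Mb. Median peak width was 941.5 bp larger with decitabine alone than without treatment, and the combination differed from chidamide alone by -1131 bp.

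A candidate explanation for the many narrow peaks of the combination list, which enters each of these contrasts, is that domains were split into several peaks. Of its 21531 pairs of neighbouring peaks less than 1 kb apart, 59.59% (58.93 to 60.24%) were both overlapped by 1 and the same untreated peak, as splitting would give, while the reverse held for 23.92% (22.84 to 25.02%) of the untreated list's 5995 pairs. Such shares are not particular to the combination list, since 1 decitabine peak overlapped both members of 66.14% of the untreated pairs and 1 chidamide peak 53.86%, and after merging the combination's median width stayed lower than the untreated one, at 2772 bp against 3421 bp. Shorter DNA fragments in this library may trim domains by a fixed length. Against the chidamide list the median span loss was similar in broad and narrow regions, at 609 and 505 bp, a ratio of 1.21. The chidamide spans themselves exceeded the untreated ones by a median of 584.5 bp in broad and 94 bp in narrow regions. That difference adds mostly to the loss in broad regions, so the ratio of 1.21 is no separate support for a fixed trim. Against the untreated list the loss was 59 bp in broad and 390 bp in narrow regions, a ratio of 0.15, which lies under the bound of 2 but is no fixed trim, so this comparison leaves fragment length open, as are the untested read depth, peak caller's settings and effect of the combined drugs.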

How the results depend on the processing

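Of 110 values computed under alternatives for 26 results, 51 stayed within 1.5 times the main count and 59 moved, where any shift of a length or width counted as a move. None of the 14 values moved with an overlap of 50% of the shorter peak or with autosomes alone. Each group has 1 library and the read depth is unknown, so no alternative separates treatment from library. No paired analysis was possible because each group has 1 library. The promoter and gene list parts and their alternatives were not run, for want of a gene table of the hg19 build. The causes of the moves were not tested, apart from what an alternative does by construction, such as dropping or joining peaks.

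A reciprocal overlap of 50% moved 9 of 14 values. Gained and lost peaks numbered 11706 and 7898 for chidamide, 4509 and 7635 for decitabine, and 28129 and 10725 for the combination, which shared 12537 peaks with the untreated list. The combination list held 24796 peaks absent from the others, and the untreated and decitabine pair held 1296 regions.

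Peaks scoring 740.475 or more moved all 26 values. Shared, gained and lost peaks numbered 10961, 894 and 633 for chidamide, 10860, 323 and 341 for decitabine, and 11255, 457 and 1644 for the combination. The combination list held 23 peaks absent from the other lists at this cut-off. All 4 lists held 9465 regions, both single-agent gained sets 107, the chidamide and combination pair 302 and the untreated and decitabine pair 374. The untreated list held 11631 peaks over 51.25 Mb with a median width of 4046 bp, the chidamide list 11855 over 57.89 Mb (4378 bp), the decitabine list 11183 over 56.48 Mb (4618 bp) and the combination list 11712 over 40.32 Mb (2958.5 bp).

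Lists limited to 20136 peaks moved 7 of 14 values. Chidamide gained 3131 peaks, decitabine lost 1079, and the combination shared 18900 and gained 1236, with 45 absent from the other limited lists. The chidamide and combination pair held 434 regions and the untreated and decitabine pair 1303.

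Merging within 1 kb moved 17 of 26 values. Chidamide gained 4029 and lost 1742 peaks, decitabine lost 1396, and the combination shared 15123, gained 4012 and lost 2353, with 1912 absent from the other lists. The chidamide and combination pair held 1285 regions. The lists covered 64.43 Mb (untreated, median width 3421 bp), 75.88 Mb (chidamide, 3447 bp), 69.83 Mb (decitabine, 3646.5 bp) and 62.36 Mb (combination, 19135 peaks, 2772 bp).

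The chidamide and combination pair exceeded the model of list length under 50% of the shorter peak (2129 against 1363.6), at 740.475 or more (302 against 55.3), with 20136 peaks (434 against 57.1), after merging (1285 against 717.1) and on autosomes (1926 against 1193.5). It fell below the model with the reciprocal overlap, at 1740 against 2015.5. The untreated and decitabine pair exceeded the model in all 6. The settings of 740.475 or more and of 20136 peaks drop peaks before the lists are compared, so another list can hold their regions below the cut. In the full lists, 1 region of the untreated and decitabine pair and 82 of the chidamide and combination pair scored 500 or more in both lists. These 2 settings therefore do not retest the same regions. Without the combination list, an alternative chosen after the data were seen, 1009 regions were held by the untreated and decitabine lists alone and 578 by both single-agent lists alone.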

Other observations

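The counts by place and distance were chosen after the data were seen, as were the tests of list length, library batch, chromosome trend and clusters. The test of clusters replaced an earlier form, whose comparison with all windows was saturated, after its result was known. The count of regions at 150 or more was set before its result was seen, and the shares and the count at 500 or more were added after it.

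The window from 51 to 52 Mb of chromosome 19 held 17 regions of the chidamide and combination pair, among them chr19:51410131-51412836 (scores of 1744.1 and 469.02) and chr19:51670088-51672754 (596.6 and 80.78). Many of the 17 scored under 100 in the combination list. Some were close neighbours, such as chr19:51412947-51414391 directly after the first of these, so the 17 may not be separate domains. In 1000 random draws of as many regions from those of any list, the fullest window had a median of 9 and at most 14 regions. No other window of the pair passed 14, and the next held 12. Of the pair's 1963 regions, 36.17% (34.04 to 38.34%) lay within 5 kb of a region of all 4 lists and 28.27% (26.29 to 30.32%) lay more than 50 kb away. Regions of the combination list alone were nearer, with 50.75% (48.98 to 52.51%) within 5 kb. Fewer of those of the untreated and decitabine pair lay within 5 kb, at 22.04% (19.05 to 25.25%). Their share beyond 50 kb, 28.17% (24.91 to 31.62%), was close to that of the chidamide and combination pair.

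The excess of regions held by the chidamide and combination lists alone could come from the length of those lists. The count of 1963 lay above all 1000 draws of the model built on length, which had a maximum of 1314, and this argues against length as the whole cause. With a reciprocal overlap of 50% the count was 1740 against 2015.5 in the model, so the excess depends on how overlap is counted. Regions scoring 150 or more in both lists numbered 463 (23.59%, interval 21.72 to 25.53%) against 131 (18.22%, 15.46 to 21.24%) for the next pair, and 82 against 1 at 500 or more, which argues against peaks near the calling threshold as the whole cause but leaves it open for the 1500 regions under 150 in at least 1 list. Library batch and treatment cannot be told apart with 1 library per group, depth is unknown, and an effect of chidamide on H3K4me3 at these places stays open as an untested hypothesis.

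The larger share of chromosome 19 in that pair might follow the high GC content of this chromosome. Chromosomes 16, 17 and 22, which are also GC-rich, held 12.58% of the pair's regions (11.15 to 14.13%), where the ratio seen on chromosome 19 would need 17.02% and the regions of all 4 lists gave 12.98%. Chromosomes 4 and 13, which are GC-poor, held 3.26% (2.52 to 4.14%) against 4.81% of the regions of all 4 lists, as such a trend would give, so the values go both ways and leave it open, and local GC content was not examined. Clusters of neighbouring regions could also raise the share, and with each 1 Mb window counted once chromosome 19 held 4.9% of the windows (3.61 to 6.49%) against a mean of 4.08% (3.5 to 4.64%) in 1000 draws of as many regions, which leaves clusters open.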
